A study of Mus musculus with 21 samples.

How the data were processed

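Exome sequencing of genomic DNA was read from lists of single-nucleotide variants (SNVs) for mouse embryonic stem cells (ESCs) and for tumours. Of the 21 samples, 18 had a list: 10 ESC libraries and 8 tumour libraries. The other 3 samples, genomic DNA of mouse embryonic fibroblasts (MEFs) and 2 wild-type blood samples, had no list of their own. DNA was captured with Agilent SureSelect per the labels. The series design names ATAC-seq for the tumours while the series title names exome sequencing, so the assay of the tumour lists is not settled by the sources used here.

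Per the submitters' processing notes, the authors used BWA, SAMtools and Picard with the mouse genome mm10, without stated versions. The SNV caller is not given in the sources used here. Per the file headers, each line of the deposited lists holds an SNV of a library against its control, with genotype, reads per allele, mean base quality, read depth, alternative-allele fraction and a somatic status for both. Every deposited line was marked as passing the caller's filter and as somatic. Even so, the control held alternative reads at 5.91 to 7.14% of the calls of an ESC library. For the tumours this was 37.4 to 38.2% in 7 libraries and 17.1% in LCDM-P9 replicate 2. The deposited annotation gave the gene, the region, the consequence on RefSeq transcripts, segmental duplications, repeats and dbSNP build 142 identifiers. The quality column was empty, so base quality was used where a quality setting was needed.

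The ESC and tumour lists were filtered differently before deposit. No ESC call had a dbSNP identifier, whereas 95.0 to 97.5% of the calls of a tumour library had one. In each ESC list no 2 calls of a chromosome were closer than 10 kb, the smallest gap per library being 10017 to 10033 bp. In the tumour lists the smallest gap was 1 bp, and 62.6 to 71.1% of the gaps were at most 10 kb. The step that spaced the ESC calls is not given in the sources used here. An ESC list therefore counts at most 1 call in 10 kb, and a site can be missing from a library because another call nearby was kept. Call numbers of ESCs and tumours were not compared with each other for these reasons.

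Each ESC list was called against 1 MEF control, and each tumour list against 1 wild-type blood control. At the 53148 calls shared by pairs of ESC lists the control values were identical in 100% of cases, and likewise at 194593 shared tumour calls, so each set shares a control. The library values at shared calls were identical in 0.324% (ESC) and 0.393% (tumours), so no 2 lists came from the same reads. The sample of 2 tumour lists, those of 2iL-P9 and 2iL-F-P9, was taken from the record that links files to samples, because the sample names in their headers differ from the labels. The name in the header of the tumour recorded as 2iL-P9 starts with F, and that of the tumour recorded as 2iL-F-P9 with Q, prefixes the labels do not explain. An exchange of these 2 tumours is therefore not excluded.

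An SNV was identified by chromosome, position, reference and alternative base, and positions are those of the files (mm10, counted from 1). A private SNV was called in 1 library and in none of the other libraries of its set (10 ESC or 8 tumour libraries). A restricted SNV was called in at least 1 library of an ESC condition and in no library of the other 4. Substitutions were folded into 6 classes by strand. The protein-changing share is the percentage of coding SNVs that are missense, stop-gain or stop-loss. Protein changes are numbered from the initiator methionine of the first RefSeq transcript listed in the annotation. Gene symbols were taken from the files: 4779 symbols occurred, of which 4533 stood in a RefSeq gene table as symbols and 217 only as synonyms.

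The 5 ESC conditions, with 2 libraries each, were compared by an exact permutation test of the F statistic over every partition of the 10 libraries into 5 pairs, which is one-sided by construction. Each condition was set against the other 4 by an exact two-sided permutation test of the difference of means (45 splits, smallest p 0.0222), with Benjamini-Hochberg adjustment over the 5 conditions, after which a single deviating condition cannot go below 0.111. Pairs of conditions give 2 against 2 libraries, where the smallest two-sided p is 0.33. Sharing of SNVs between libraries was measured by the Jaccard index (shared calls over the union of 2 lists), and same-condition pairs were compared with other pairs by an exact two-sided permutation test over the same partitions. Gene lists, 11 in number, were tested by two-sided Fisher's exact tests of list membership among private SNVs against all other gene-assigned ESC SNVs, with Benjamini-Hochberg adjustment over the 11 lists. The 3 A2iL-P9 tumours were compared with the other 4 P9 tumours (35 splits) and with the 2 LCDM-P9 tumours (10 splits, smallest p 0.1) by exact two-sided permutation tests. The overlap of tumours with the ESC condition of the same name was tested over 120 relabellings of the conditions. The threshold was 0.05, and intervals of shares of single libraries are 95% Wilson intervals, which cover counting error only. The labels do not say that replicates came from separate cultures or animals, so the p-values measure the spread between these samples.

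Groups, tests, gene lists, the rule for named genes and the first set of alternatives were fixed before the data were examined. The rule named, for each ESC condition, up to 5 genes with most protein-changing SNVs in both its libraries and in no library of the other 4, filled up by genes with most private protein-changing SNVs. For each tumour group it named up to 4 genes with most protein-changing SNVs found in no other tumour group, and from each gene list up to 4 genes with a private or restricted protein-changing ESC SNV. It also named up to 10 genes with private protein-changing SNVs in 3 or more ESC conditions, of which there were none. Ties were broken by the number of SNVs and then by the alphabet. Genes named outside this rule are said to have been chosen after their values were seen. Atm, Wrn, Parp1, Egfr, Kmt2c, Rb1, Sufu, Ptk2 and Yes1 are outside it as well. They were named afterwards, where the ESC sites of their fixed lists are counted. Genes of olfactory, vomeronasal and zinc finger families and of Gm and Rik models belong to multigene families, in which reads can come from related genes. Named changes in annotated segmental duplications or repeats are described as uncertain.

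The preset alternatives were at least 20 reads, at least 5 alternative reads, calls at or above the median base quality (37 in both sets), autosomes only, SNVs within 10 bp of another left out, tumour SNVs within 100 bp of an ESC SNV, privacy over all 18 libraries, the label number as a block, other indices of sharing, and each library left out in turn. Alternatives added after seeing the data were sites outside segmental duplications and repeats, a mean base quality of at least 30, tumour sites without a dbSNP identifier, sites called in exactly 2 libraries, the signalling list without Parp1, the 2iL-P9 and 2iL-F-P9 tumours exchanged, label numbers compared among pairs of different conditions only, and neighbourhoods of 10 kb. Under the last, a private SNV has no call of another library within 10 kb, a restricted SNV has none of another condition, and calls within 10 kb count as shared.

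The tests were tested on simulated data, 40 sets built from the 4358 distinct ESC sites with known private SNVs. With no addition, the F test passed the threshold in 0 of 40 sets and the test of 2iL-F against the rest in 3 of 40 before and 0 of 40 after adjustment over the 5 conditions. With 200 private sites added to the 2iL-F libraries, the F test passed in 17 of 40 sets and the test of 2iL-F against the rest in 40 of 40 before and 0 of 40 after adjustment. With each condition a step of 50 sites higher than the one before, the F test passed in 40 of 40. The F test therefore has little power for a single deviating condition, and the adjusted test has none. Analyses were run in Python 3.11.15 with NumPy 2.4.6, SciPy 1.17.1 and matplotlib 3.10.9.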

Results

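The series compared genome stability in mouse ESCs kept in 5 culture conditions, and in tumours of mice made from ESCs by tetraploid complementation, in which the embryo proper derives from the injected ESCs. The cells were of the strain written C57BL6X129S6F1 in the labels. SL is medium with 15% serum and leukaemia inhibitory factor (LIF, 1000 IU). 2iL is serum-free N2B27 medium with LIF, the GSK3 inhibitor CHIR99021 (3 µM) and the MEK inhibitor PD0325901 (1 µM). A2iL has CHIR99021 (3 µM) and the Src inhibitor CGP77675 (1.5 µM), and LCDM has CHIR99021 (3 µM) with the additives written Dim and Mih in the labels (2 µM each). All of these were grown on feeder cells, and 2iL-F is the 2iL medium without feeders. Each condition had 2 libraries, numbered 3 and 5 in the labels. Tumour libraries carry an ESC condition and P9 or P14 in their names: 1 for 2iL-P9, 3 for A2iL-P9, 1 for A2iL-P14, 2 for LCDM-P9 and 1 for 2iL-F-P9. What 3, 5, P9 and P14 stand for is not stated in the labels.

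The ESC lists held 1762 to 1858 SNVs per library at a median depth of 54 to 72 reads (59 to 64 in the MEF control). Their median alternative-allele fraction was 0.235 to 0.264, and 45.4 to 47.4% of the calls lay in segmental duplications. The tumour lists held 3634 to 10325 SNVs at a median depth of 28 to 39 reads. In both sets the fewest alternative reads behind a call were 2.

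Whether culture conditions differ in the number of SNVs was asked first. The same coding changes recurred across conditions. Ccne1 R134C, in cyclin E1, which drives entry into S phase, was called in all 10 libraries at fractions of 0.293 to 0.681, and Dnmt3b K383R, in a de novo DNA methyltransferase, in all 10 at 0.168 to 0.261. These genes, and Pold1, Cdk4 and Mad2l1 below, were named after their values were seen. The mean number of calls per library was 1787.5 ± 36.1 (SD, n = 2) in SL, 1834 ± 33.9 in 2iL, 1830 ± 12.7 in A2iL, 1789 ± 8.49 in LCDM and 1822 ± 8.49 in 2iL-F. The 5 conditions did not differ beyond the spread between libraries (exact permutation F test, one-sided p = 0.285, n = 2 each). Against the other 4 conditions, SL differed by -31.25 calls (-5.75 without SL library 5, -56.75 without SL 3) and 2iL by 26.9 (2.875 without 2iL 5, 50.9 without 2iL 3). The lowest unadjusted p was 0.156 (exact permutation, two-sided), and adjusted over the 5 conditions 0.444. The adjusted p of a single deviating condition cannot go below 0.111, so it is no evidence that the conditions are alike. With at least 20 reads, LCDM differed from the other 4 by -85 calls, at that floor (exact permutation, adjusted p = 0.111). The F test did not pass there (exact permutation p = 0.222). The LCDM libraries also had the lowest median depths, 54 and 56 reads. Relative to 2iL, the mean differed by -12 calls in 2iL-F, by -46.5 in SL, by -4 in A2iL and by -45 in LCDM, in tests of 2 against 2 libraries that cannot go below an exact p of 0.33. Because no 2 ESC calls of a list lay within 10 kb, these numbers count spaced calls and can hide differences between closely placed SNVs.

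**Figure D1:**
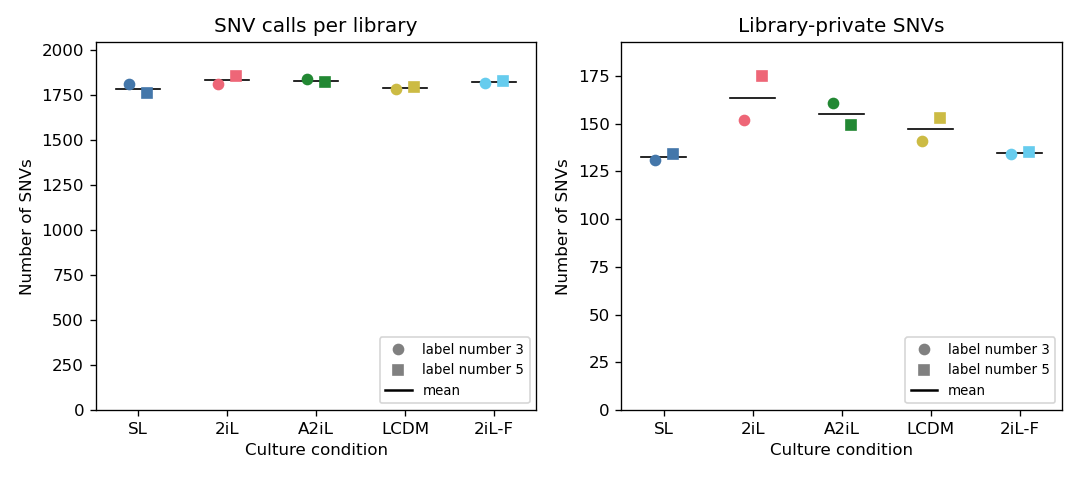
Number of SNV calls (left) and of private SNVs (right) per ESC library by culture condition, with circles for label number 3, squares for number 5 and bars for means. All libraries lie between 1762 and 1858 calls, and private SNVs range from 131 in SL to 175 in 2iL.

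Private SNVs were compared next. Of 4358 distinct ESC sites, 636 (14.6%) were called in all 10 libraries and 1465 (33.6%) in 1. Sites called in all 10 had a median fraction of 0.319, against 0.18 for private sites. The median depth of private calls was 25 to 36 reads per library, against 54 to 72 for all calls. Of the private sites 25.9% lay in repeats, against 7.08% of those called in all 10. Exonic sites numbered 172 of the 1465 private and 214 of the 636 called in all 10. Whether private sites were missed in other libraries for lack of reads was not tested. Private SNVs numbered 132.5 ± 2.12 (SD, n = 2) in SL, 163.5 ± 16.3 in 2iL, 155 ± 8.49 in A2iL, 147 ± 8.49 in LCDM and 134.5 ± 0.707 in 2iL-F. The difference among conditions did not pass the threshold (exact permutation F test, one-sided p = 0.0614). It passed without 2iL library 3 (exact permutation p = 0.0212). The 2iL libraries had 21.25 more private SNVs than the mean of the other 8 (142.25), with both libraries above it (exact permutation, two-sided p = 0.0667, adjusted over 5 conditions 0.33, where a single condition cannot go below 0.111). The difference was 9.75 without 2iL library 5 and 32.75 without 2iL library 3. With a base quality of at least 30, a setting added after seeing the data, it was 30 (exact permutation, adjusted p = 0.111, that floor). Both 2iL libraries, with 147 and 166 such private SNVs, then lay above all others. The F test did not pass in that setting (exact permutation p = 0.276). Relative to 2iL, private SNVs differed by -29 in 2iL-F, -31 in SL, -8.5 in A2iL and -16.5 in LCDM, where 2 against 2 libraries cannot go below an exact p of 0.33. Of the 1465 private sites, 721 (49.2%) had no call of another library within 10 kb. Counted that way, private SNVs numbered 61 ± 8.49 (SD, n = 2) in SL, 81 ± 11.3 in 2iL, 78 ± 8.49 in A2iL, 69 ± 2.83 in LCDM and 71.5 ± 0.707 in 2iL-F (exact permutation F test, one-sided p = 0.120).

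Few protein-changing SNVs were found in both libraries of a condition and in no other: 4 in 2iL, 3 in LCDM, 1 in 2iL-F and 0 in SL and A2iL. In 2iL these were Ccnb2 T294M (chromosome 9, position 70410215, exon 7), Micall2 G234R (chromosome 5, position 139716787, exon 6), Nsrp1 A196V (chromosome 11, position 77048380, exon 6) and Olfr1480 Y192H (chromosome 19, position 13530248), the last an olfactory receptor in a segmental duplication and so uncertain. Ccnb2 encodes the mitotic cyclin B2, and its change had fractions of 0.167 (6 of 36 reads) and 0.07 (4 of 57). All 8 other libraries carried another call within 10 kb of it, the nearest 61 bp away, so its absence there is not established. Micall2, whose product acts at cell junctions, had fractions of 0.083 and 0.061, Nsrp1, a splicing regulator, 0.057 and 0.077, and Olfr1480 0.036 and 0.03. None of these 3 had a call of another library within 10 kb.

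In LCDM the changes were Nol8 E464K (chromosome 13, position 49661807, exon 7), Slc7a6os S263C (chromosome 8, position 106202236, exon 4) and Arpp21 T390M (chromosome 9, position 112127433, exon 12). Nol8, a nucleolar protein, had fractions of 0.247 (19 of 77 reads) and 0.328 (22 of 67). Slc7a6os had 0.269 (36 of 134) and 0.244 (33 of 136), and Arpp21, a cAMP-regulated phosphoprotein, 0.125 and 0.353 at depths of 24 and 17. In 2iL-F, Slc4a10 R30H (chromosome 2, position 62158246, exon 2), in a sodium bicarbonate transporter, had 0.127 (8 of 63) and 0.129 (11 of 85). No other library had a call within 10 kb of any of these 4 sites.

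The remaining named changes were private to a library. In SL they were Adam9 G778D, Ccdc155 T190N, Clip3 M288L, Gbp10 P158L and Gm15284 I5V, of which Clip3 had most support outside duplications (7 of 43 reads). In A2iL they were Akap8l Y126S (6 of 24 reads), Elf1 I300S (4 of 82), Gm10220 N137K, Gm10324 F551Y and a stop gain in the splicing factor Srsf5, R257X (chromosome 12, position 80949937, exon 8, 5 of 60 reads in library 3). In 2iL BC003331 S120N was added (16 of 71 reads), in LCDM 4930444G20Rik V428I and Gm13152 Q121P, and in 2iL-F Fam120a D696A, Gm13157 E270D, Olfr101 S208P and Slc25a51 T92R and D30V. Akap8l, Ccdc155, Clip3, Fam120a, Gbp10 and Olfr101 had no call of another library within 10 kb. Srsf5 had one in 4 other libraries, the nearest 32 bp away. Elf1 had one in 1 library and Adam9 in 3, and BC003331, Gm10220, Gm10324, Gm13152, Gm13157, Gm15284, 4930444G20Rik and Slc25a51 had one in all 9, so that privacy of these changes is uncertain. The Gm, Rik and Olfr genes belong to multigene families. Gbp10 (8 of 258 reads), Slc25a51, 4930444G20Rik and the Gm changes lie in segmental duplications, so the calls themselves are uncertain as well. No gene had private protein-changing SNVs in 3 or more conditions, 7 had them in 2 and 87 in 1. Akap8l Y126S, in A2iL library 5, and Elf1 I300S and Gm10220 N137K, in A2iL library 3, are T>G changes. Private T>G calls had median base qualities of 16 and 26 in these libraries. Of the 40 calls behind the named ESC changes, 38 had at least 20 reads, 28 at least 5 alternative reads and 26 lay outside segmental duplications and repeats. A base quality of at least 30 was met by 38, and which calls fell below it is not given here.

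Whether libraries of a condition hold the same SNVs was asked next. Pairs of libraries of the same condition shared more SNVs than other pairs, with a mean Jaccard index of 0.495 against 0.482 (difference 0.0126, exact permutation over partitions, two-sided p = 0.00317). The index was 0.520 for 2iL-F, 0.516 for A2iL, 0.491 for SL, 0.478 for 2iL and 0.468 for LCDM, so that 3 of the 5 conditions lay above the mean of other pairs. The difference missed the threshold without A2iL library 3 (p = 0.0878), A2iL 5 (0.119), 2iL-F 3 (0.114) or 2iL-F 5 (0.0974), all by the same exact permutation test. Sites called in exactly 2 libraries were more often those of 1 condition, with 21 sites per same-condition pair against 11.95 per other pair (exact permutation, two-sided p = 0.00106, the smallest possible). Restricted to sites with no call of another library within 10 kb, the means were 12.2 and 4.15 (exact permutation p = 0.00106). Sites in both libraries of a condition and no other numbered 30 in 2iL, 21 in LCDM, 20 in 2iL-F, 18 in SL and 16 in A2iL, of which 20, 15, 14, 6 and 6 had no call of another condition within 10 kb. Libraries with the same label number differed from other pairs by -0.00487 (exact permutation, two-sided p = 0.0556), and the difference passed without SL library 3 (exact permutation p = 0.0476) or LCDM library 3 (0.0317). The other pairs include those of the same condition, which lowers this value. Among pairs of different conditions it was -0.00260 (exact permutation p = 0.188, smallest possible 0.0625).

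The substitution spectrum was dominated by C>T changes in all conditions, at 37.5 to 40.2% of all calls per library, and transitions made up 58.6 to 61.8%. No class differed among conditions, with a lowest adjusted p over the 6 classes of 0.760 for all calls and 0.717 for private calls (exact permutation F tests, one-sided). The transition share did not differ either (exact permutation p = 0.851 for all calls and 0.273 for private calls).

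Protein-changing SNVs made up a smaller part of the private coding SNVs in A2iL, at 45 ± 7.07% (SD, n = 2), than in SL (65.5 ± 1.68%), 2iL (62.1 ± 1.18%), 2iL-F (61.5%) or LCDM (60%), both libraries being at the same value in the last 2. The difference among conditions passed the threshold (exact permutation F test, one-sided p = 0.00317). It rests on 4 to 19 protein-changing SNVs per library, and the Wilson interval of A2iL library 5, with 4 of 10, ran from 16.8 to 68.7%. It was lost for calls at or above the median base quality (exact permutation p = 0.115), outside segmental duplications and repeats (0.966) and for private SNVs with no call of another library within 10 kb (0.124). Over all coding calls the share did not differ (exact permutation p = 0.293), but it did outside segmental duplications and repeats (exact permutation p = 0.0233).

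The alternative-allele fraction of private SNVs was lowest in 2iL, at 0.148 ± 0.00636 (SD of the library medians, n = 2), against 0.198 in A2iL, 0.195 in LCDM, 0.183 in SL and 0.177 in 2iL-F. The conditions did not differ past the threshold in private calls (exact permutation F test, one-sided p = 0.0614) or in all calls (0.0899). With at least 20 reads both passed (exact permutation p = 0.0307 and 0.0222). For private calls p rose to 0.426 at or above the median base quality, 0.374 with a base quality of at least 30, 0.217 outside segmental duplications and repeats and 0.251 with no neighbour within 10 kb (exact permutation). For all calls the same first 3 settings gave 0.0519, 0.0635 and 0.0730 (exact permutation).

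The lists for DNA repair, the cell cycle and pluripotency held 5, 7 and 5 ESC sites, numbers that were not compared with the rate over all genes. Of the DNA repair and checkpoint list, the checkpoint kinase gene Atm and the helicase gene Wrn had 2 sites each and Parp1, of strand-break repair, had 1, all intronic, all private and at depths of 5 to 37 reads. They made up 0.607% of the private and 0% of the other gene-assigned SNVs (5 of 824 private sites, Fisher's exact test, two-sided, adjusted p over 11 lists 0.0258). The 2 Atm sites lay 4185 bp apart in libraries SL 5 and 2iL-F 3, and with private SNVs that have no such neighbour the adjusted Fisher's exact p was 0.106 (3 of 5 sites). Outside segmental duplications and repeats it was 0.403.

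The pluripotency list had 5 sites, 1 of them private (Fisher's exact test, adjusted p = 0.916): Nanog P61H (chromosome 6, position 122711568, exon 2), in a core pluripotency factor, was read in 7 of 21 reads of 2iL library 5. The 9 other libraries all carried Nanog P72T, 32 bp away, at fractions of 0.143 to 0.359. The p53 and cell cycle list showed the same arrangement. Cdk4 A23T was called in 8 libraries (0.2 to 0.33) and V51I, 84 bp away, in the other 2, A2iL 3 and LCDM 5. Mad2l1, of the spindle checkpoint, had T176A in 3 libraries and a synonymous SNV 4307 bp away in the 7 others. Because a list keeps at most 1 call in 10 kb, neither change of such a pair can be taken as absent from the remaining libraries. This list had 2 of 7 sites private (adjusted Fisher's exact p = 1).

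Tumour suppressors and oncogenes had 6 of 8 sites private (adjusted Fisher's exact p = 0.0619), in Egfr, Kmt2c, Pdgfra, Rb1 and Sufu. Only Pdgfra A530S, in a receptor tyrosine kinase (chromosome 5, position 75177674, exon 11), changed the protein, with 4 of 89 reads in 2iL library 5. The list for MAPK, Wnt and Src signalling had 3 of 3 private (adjusted Fisher's exact p = 0.0883), in Ptk2, Yes1 and Parp1, which the list as fixed also holds although it is a DNA repair gene. The counts were 5 of 7 for DNA methylation and chromatin genes (adjusted p = 0.0928), 3 of 4 for telomere maintenance genes (0.188), and 0 of 1 for mismatch repair, base excision repair and replicative polymerase genes (1), all by Fisher's exact test. With private SNVs that have no neighbour within 10 kb, 3 of these lists passed: tumour suppressors (adjusted Fisher's exact p = 0.00614), chromatin (0.0166) and MAPK, Wnt and Src (0.0209), again on 6, 5 and 3 private sites. These numbers stayed the same while the private gene-assigned sites fell from 824 to 510, so the rise in their shares comes from the smaller total. The tumour suppressor and chromatin lists are not independent, as both count the 2 Kmt2c sites, which lie in repeats at depths of 7 and 6 reads. The other private chromatin sites had 8, 12 and 22 reads, and the other private tumour suppressor sites 8 to 89. Without Parp1 the signalling list had 2 of 2 sites private and did not pass (adjusted Fisher's exact p = 0.188, and 0.0823 with no neighbour within 10 kb). Outside segmental duplications and repeats none of the 3 passed (adjusted Fisher's exact p = 0.749, 0.819 and 0.405). The polymerase site was a synonymous SNV of Pold1, a replicative polymerase gene, in all 10 libraries.

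Of the lists of multigene families, the olfactory and immune ones made up less of the private than of the other SNVs. Olfactory and vomeronasal receptor genes had 40 private of 169 sites, 4.85% of the private against 8.16% of the other SNVs (odds ratio 0.574, Fisher's exact test, adjusted p = 0.0258), and 70.4% of their sites lay in segmental duplications. The genes of the major histocompatibility complex and innate immune clusters had 12 of 63, 1.46% against 3.23% (odds ratio 0.443, adjusted Fisher's exact p = 0.0371). Neither passed outside duplications and repeats (adjusted Fisher's exact p = 0.828 and 0.819) or among protein-changing SNVs only (1 for both). With private SNVs that have no neighbour within 10 kb the odds ratios fell to 0.149 and 0.0581, which clustered genes do by construction. With restricted in place of private SNVs the second did not pass (adjusted Fisher's exact p = 0.124). Mucins and large repeat proteins had 5 of 16 private (adjusted Fisher's exact p = 1). The named members were Olfr101 S208P, Olfr1085 S264Y, Olfr1480 Y192H, Olfr1505 F28L, Hrnr S1048N and Klra10 P219Q. Olfr1480, Olfr1505, Hrnr and Klra10 lie in segmental duplications, so their calls are uncertain, whereas Olfr101 and Olfr1085 lie outside annotated duplications and repeats. Calls of other libraries lay within 10 kb of Klra10 (9 libraries, nearest 172 bp), Hrnr (5 libraries) and Olfr1085 (1 library, 231 bp), so that these changes are not established as private. For every list, the share among private SNVs did not differ between the 5 conditions (exact permutation F tests, adjusted p = 1 over the 11 lists). Private sites numbered 0 for mismatch repair, 1 for pluripotency, 2 for p53 and 3 each for telomere and signalling genes. These lists could hardly have shown a difference.

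Tumours were compared with wild-type blood, with A2iL-P9 as the only group of 3. Nearly all tumours carried the same sites: 7639 SNVs were called in all 7 tumours other than LCDM-P9 replicate 2, and 97.1 to 97.5% of the calls of those 7 had a dbSNP identifier. A2iL-P9 tumours had 9908 ± 138 calls (SD, n = 3), the 2iL-P9 tumour 10325, the 2iL-F-P9 tumour 9752 and the LCDM-P9 tumours 9858 and 3634. The difference between A2iL-P9 and the other 4 P9 tumours was 1515.75 calls (exact permutation, two-sided p = 0.771), and -70.3 without LCDM-P9 replicate 2 (exact permutation p = 0.9). Against LCDM-P9 alone it was 3162 (exact permutation p = 0.2, smallest possible 0.1), 50 without LCDM-P9 replicate 2 (p = 0.75) and 6274 without replicate 1 (p = 0.25). Private SNVs numbered 121 ± 11 (SD, n = 3) in A2iL-P9, 164 in 2iL-P9, 91 in 2iL-F-P9 and 134 and 3083 in LCDM-P9, a difference of -746.7 (exact permutation p = 0.657), and -8.33 without LCDM-P9 replicate 2 (exact permutation p = 0.8). The file headers leave open an exchange of the 2iL-P9 and 2iL-F-P9 tumours, which would not change these comparisons, as both tumours are in the same group. Among sites without a dbSNP identifier A2iL-P9 had 266 ± 22.5 calls (SD, n = 3) and the other P9 tumours 248.25 ± 48.7 (n = 4), a difference of 18.1 (exact permutation p = 0.657). It rests on LCDM-P9 replicate 2, with 183 calls. The 2iL-P9, LCDM-P9 replicate 1 and 2iL-F-P9 tumours had 286, 285 and 239, against 241, 274 and 284 in A2iL-P9. Private SNVs at these sites numbered 34 ± 8.72 in A2iL-P9 (SD, n = 3) and 70 ± 58.8 in the others (n = 4), a difference of -36 (exact permutation p = 0.457). The others had 45 in 2iL-P9, 21 in 2iL-F-P9 and 59 and 155 in LCDM-P9, so this too rests largely on LCDM-P9 replicate 2. Against LCDM-P9 alone, with 59 and 155, the difference was -73 (exact permutation p = 0.1, the smallest possible), all 3 A2iL-P9 tumours (28, 44 and 30) being lower. The A2iL-P14 tumour, with 10105 calls and 119 private SNVs, differed from the A2iL-P9 mean by 197 and -2.33, values of 1 library without a test.

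**Figure D2:**
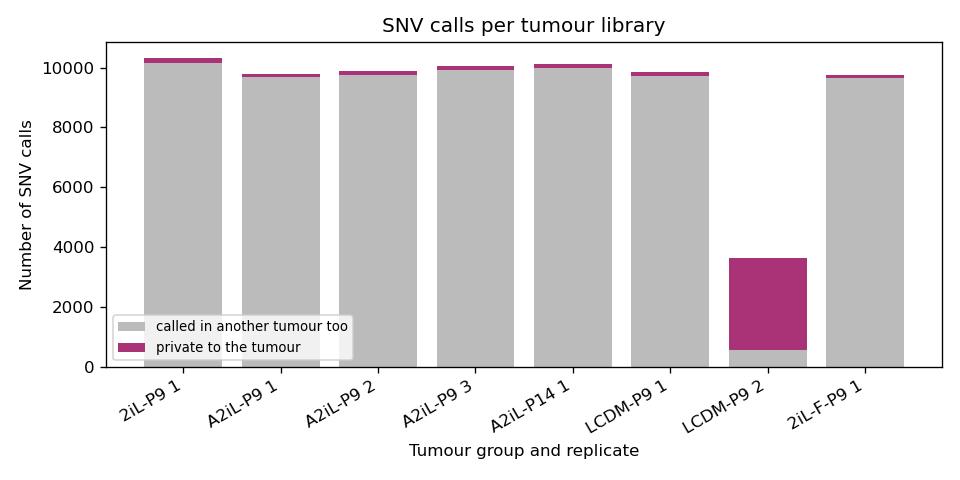
SNV calls per tumour library, with calls also found in another tumour in grey and private calls in purple. In 7 tumours 91 to 164 calls were private, whereas 3083 of the 3634 calls of LCDM-P9 replicate 2 were.

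The LCDM-P9 replicate 2 tumour shared 368 (4.82%) of the 7639 sites common to the other 7, and 84.8% of its calls were private (Wilson 95% interval 83.6 to 86.0%). Its median fraction was 0.8, against 0.429 to 0.436 in the others. Its protein-changing SNVs included 7 in Pcdhgb1, 6 each in Pcdhga4 and Pcdhga11, clustered protocadherin genes of neuronal cell recognition on chromosome 18, and 6 in the thyroglobulin gene Tg on chromosome 15. All of these had dbSNP identifiers and fractions of 0.923 to 1. Without an identifier, and named after its values were seen, this tumour carried Nsd1 G950R, in a histone methyltransferase (chromosome 13, position 55247126, exon 5, 38 of 98 reads), and a stop gain in the growth factor receptor gene Egfr, S306X (chromosome 11, position 16871003, exon 8, 25 of 123 reads). Both were picked because their genes are on the chromatin list or the tumour suppressor and oncogene list. They are among 42 private protein-changing SNVs without an identifier in this tumour.

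The other tumour groups had few protein-changing SNVs of their own: 8 in 2iL-P9, 27 in A2iL-P9, 5 in A2iL-P14 and 9 in 2iL-F-P9, of which 4, 12, 2 and 5 had no dbSNP identifier. The 2iL-P9 tumour had changes in Gm1527, Gm3558, Gpr31b and Lima1 (G378S, 3 of 14 reads), the last an actin-binding protein, all but Gm3558 at known dbSNP sites. Of the A2iL-P9 tumours, replicate 2 alone had the laminin subunit change Lama3 N2113S (3 of 34 reads), Zfp112 E19K, Gm16432 R5Q and Vmn1r168 F221I. Zfp112 A27T was called in replicates 1 and 2 and Vmn1r168 P297H in 1 and 3. Of these only Vmn1r168 F221I was no dbSNP site, and the Zfp112 and Vmn1r168 sites each had 1 alternative read in the control. The A2iL-P14 tumour had BC048546, Gsap R31G, Mroh2a A1665S and Olfr1395 L131R, of which only the last was no dbSNP site. The 2iL-F-P9 tumour had a stop loss in Cdv3, X282Q, with Dnttip2 G398D, Fam220a G18A and G19D and Prr36 A921E. The Dnttip2 and Fam220a changes are known dbSNP sites, and both Fam220a sites had 1 alternative read in the control. Gm3558 and Mroh2a had 1 such read as well. Zfp, Vmn, Olfr and Gm genes are members of multigene families. The Gm1527, Gm3558, Gm16432, Vmn1r168, Gpr31b (4 of 87 reads) and Cdv3 (9 of 208) sites lie in segmental duplications and that of Dnttip2 (3 of 14) in a repeat, so these calls are uncertain, whereas the Zfp112 and Olfr1395 sites lie outside annotated duplications and repeats. Olfr1395 L131R is a T>G change, however, and the private T>G calls of the A2iL-P14 tumour had a median base quality of 17. Only 5 of these 23 reached 30. Of the 46 calls behind the named tumour changes, 39 had at least 20 reads, 33 at least 5 alternative reads and 37 lay outside segmental duplications and repeats. A base quality of at least 30 was met by 41.

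No difference was found between the spectrum of the A2iL-P9 tumours and that of the other P9 tumours, with C>T at 41.8 ± 0.279% (SD, n = 3) against 41.6 ± 0.440% (n = 4) of all calls. The lowest adjusted p over the 6 classes was 0.886 for all calls and for private calls (exact permutation, two-sided). Most calls are dbSNP sites shared by the tumours, so the spectrum of all calls says little about new SNVs. Without dbSNP sites the lowest p was that of T>A, at 6.15 ± 0.426% (SD, n = 3) against 8.66 ± 2.07% (n = 4, exact permutation p = 0.0571, adjusted over the 6 classes 0.343). Among private calls at these sites the lowest adjusted p was 0.571 (exact permutation).

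By chromosome, dbSNP sites outside segmental duplications that were called in all 7 other tumours with at least 10 reads (6655 sites) had similar fractions in each tumour apart from LCDM-P9 replicate 1. In that tumour the median fraction was 0.367 on chromosome 2 (360 sites), against 0.452 to 0.458 in the other 6, and 0.393 on chromosome 16 (130 sites), against 0.449 to 0.477. Its read depth over the control, relative to the median of its sites, was 0.33 (log2) on chromosome 2 and 0.22 on chromosome 16, against 0.01 to 0.08 and -0.08 to 0.03 in the others.

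**Figure D3:**
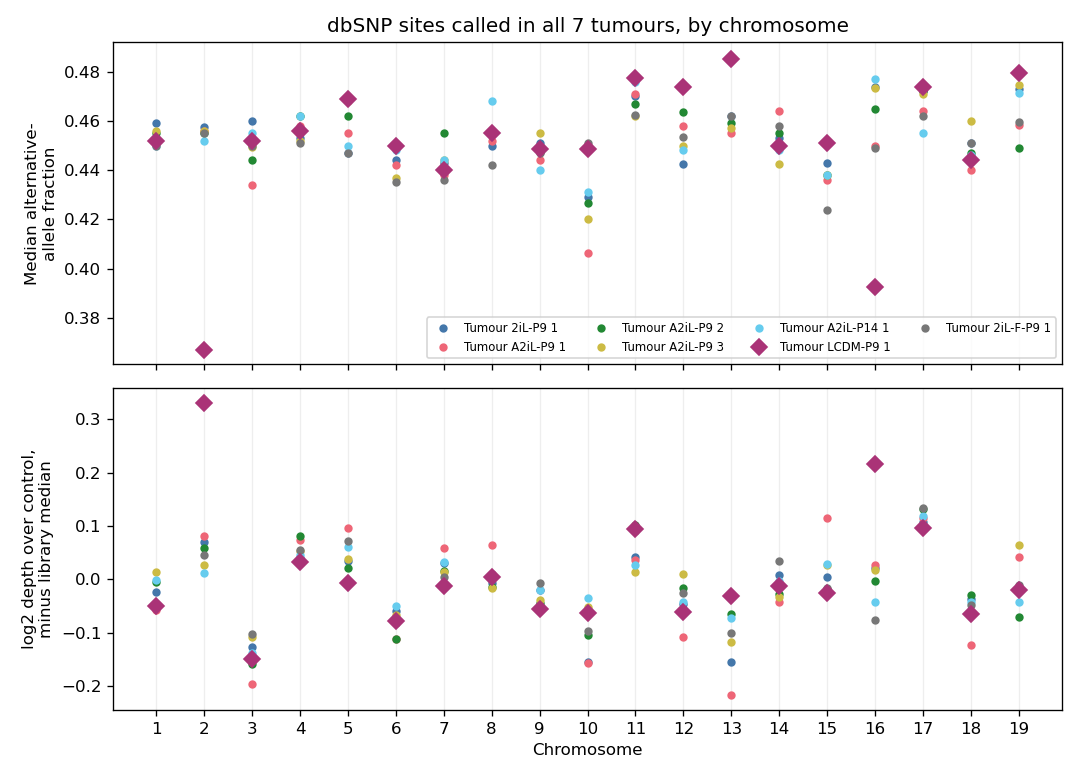
Median alternative-allele fraction (top) and log2 read depth over the control relative to the library's median (bottom) per chromosome, for 7 tumours, with LCDM-P9 replicate 1 as large diamonds. That tumour lies apart on chromosome 2 (0.367 and 0.33) and chromosome 16 (0.393 and 0.22).

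Whether tumours carry the SNVs of the ESC condition they are named after was asked last. On average 1.01% of the SNVs restricted to the ESC condition of the same name were found in a tumour, against 1.13% of those restricted to the other conditions (difference -0.126 percentage points, exact permutation over 120 relabellings, two-sided p = 0.658). With the 2iL-P9 and 2iL-F-P9 tumours exchanged the difference was -0.0619 (exact permutation p = 0.867). In counts, the 2iL-P9 tumour held 3 of the 357 sites restricted to 2iL, each A2iL tumour 4 of the 326 of A2iL, the LCDM-P9 tumours 4 and 0 of the 315 of LCDM, and the 2iL-F-P9 tumour 3 of the 289 of 2iL-F. The ESC and tumour sets had 207 sites in common, of 4358 and 15030 distinct sites. The removal of dbSNP sites and the spacing of calls in the ESC lists limit this overlap, and the labels do not say that the tumours came from these ESC libraries.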

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

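All tests of explanations in this part were chosen after the results were seen. Of 130 measures searched for a library far from the others of its set, 22 had one, whereas chance gives about 1 in 20 (6.5). Of the 22, 11 come from LCDM-P9 replicate 2 and 4 from LCDM-P9 replicate 1, on measures that depend on each other. The other 7 are close in number to 6.5, which does not show that each arose by chance. Of these, 3 are chromosome depths of A2iL-P9 replicate 1, and 1 is the T>G share of ESC library A2iL 5, described below.

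The tumour LCDM-P9 replicate 1 stood apart from the other 6 tumours on chromosome 2, with a median alternative-allele fraction of 0.367 and a log2 depth of 0.33, and on chromosome 16, with 0.393 and 0.22. A capture or depth bias touches both alleles alike, but the fraction differed from the mean of the others by -0.0883 on chromosome 2 and -0.0723 on chromosome 16, more than 3 SD of the others. A few badly mapped sites are argued against by the 5-Mb bins, of which 95.5% (21 of 22) and 91.7% (11 of 12) lay below the others' median. A gain, in part of the cells, of the homologue that lacks the alternative alleles may explain both: it predicts log2 depths of 0.29 and 0.23 from the fractions, beside observed differences of 0.28 and 0.22 (SD over other chromosomes 0.04). This would be 0.441 and 0.344 extra copies per cell, a hypothesis found and tested on the same data, and LCDM-P9 replicate 2 was not measured at these sites.

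The tumour LCDM-P9 replicate 2 differed from the other 7 in calls (3634), private calls (3083), median fraction (0.8, and 0.933 for private calls), T>A (6.85%) and T>G shares (7.51%) of all calls, T>C share of private calls (30.7%) and protein-changing share (34.2%, Wilson 95% interval 31.4 to 37.1%). Among sites without a dbSNP identifier it differed in calls (183), private calls (155) and C>A share (8.74%). Its own calls had a median depth of 39, against 28 to 38 in the others. These are mostly different sites, and the control was deeper there too, at a median of 45 against 37 to 38. Depth at the shared sites it lacks was not measured, so lower read depth there cannot be decided. Loss of a homologue of the shared genome is argued against by its calls with fractions over 0.9. Only 9.65% of them were called in another tumour (170 of 1762, Wilson interval 8.36 to 11.1%), far below the 50% such a loss would need. Another inherited background, or another animal, stays open as a candidate explanation, since 95.0% of its private calls (2928 of 3083, Wilson interval 94.1 to 95.7%) had a dbSNP identifier and its dbSNP calls filled 131 of the 5-Mb bins against 360 to 366 in the others. The tables do not separate a different cross or strain segment from an exchanged sample.

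In the ESC library A2iL 5, T>G changes made up 35.6% of the private calls (53 of 149, Wilson interval 28.3 to 43.5%) against 6.72 to 17.6% in the other 9, and their median base quality was 16. With a base quality of at least 30, only 8 of its 101 private calls were T>G. Private T>G calls also had low median base quality in ESC libraries 2iL-F 5 (21) and A2iL 3 (26) and in the tumours A2iL-P14 (17) and A2iL-P9 replicate 2 (21). In the tumour 2iL-F-P9, T>A changes made up 33.3% of the private calls without a dbSNP identifier (7 of 21, Wilson interval 17.2 to 54.6%). The tumour A2iL-P9 replicate 2 had the highest median fraction of chromosome 7, at 0.455. The tumour A2iL-P9 replicate 1 had a log2 depth of 0.064 on chromosome 8, of 0.11 on chromosome 15 and of -0.12 on chromosome 18. The ESC library SL 3 had a log2 depth of 0.16 on chromosome 14.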

How the results depend on the processing

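The settings outside segmental duplications and repeats, base quality of at least 30, sites without a dbSNP identifier, 10-kb neighbourhoods, the list without Parp1, the exchanged tumours and number sharing between conditions were chosen after the data were seen. Over 50 results and 574 alternative values, 521 kept their side of the threshold and, where the result has a sign, their direction. This count is no measure of robustness, because many alternatives could not pass. Exact permutation tests of a single deviating condition, adjusted over the 5, cannot go below 0.111. Those of 2 against 2 libraries cannot go below 0.33. Exceptions follow, and the cause was not tested unless stated. With at least 20 reads, calls against the rest turned to 3.75 for SL and -0.625 for 2iL-F, A2iL minus 2iL calls to 34.5 and private SNVs of LCDM to -7.75, and the F tests of allele fraction passed (exact permutation p = 0.0222 for all and 0.0307 for private calls). At or above the median base quality, calls turned to -60.25 for A2iL and 69.1 for LCDM and private SNVs of A2iL to -2.5, and the private protein-changing share lost its call (0.115). Outside duplications and repeats, 2iL-F calls turned to -1.75 and private LCDM SNVs to -5.875, the protein-changing share passed for all calls (0.0233) and was lost for private calls (0.966), label-number sharing passed at -0.00767, and list differences in percentage points were 0.721 for DNA repair, 0.121 for pluripotency, -0.587 for olfactory and -0.714 for MHC genes (DNA repair, olfactory and MHC lost). With base quality of at least 30, private A2iL SNVs turned to -11.25. With 10-kb neighbourhoods, private LCDM SNVs turned to -3.875, the private protein-changing share was lost (0.124), and list differences were 0.483 for DNA repair (lost), 0.128 for p53 (turned), 0.588 for MAPK, Wnt and Src, 0.875 for chromatin and 1.07 for tumour suppressors (passed). Shares change by construction there: clustered families lose private sites, and the 3 lists that passed kept theirs while the total fell; without Parp1 the MAPK, Wnt and Src list did not pass (0.392, adjusted Fisher's exact p = 0.0823). Among protein-changing SNVs only, with few sites left, differences were 0.646 for pluripotency and for mucins, -0.334 for chromatin, -3.40 for olfactory and -3.37 for MHC genes (both lost). The DNA repair, mismatch repair, MAPK, Wnt and Src, and telomere lists had no such site and gave no value. Restricted in place of private SNVs gave -1.45 for MHC genes (lost, adjusted Fisher's exact p = 0.124). Without dbSNP sites, A2iL-P14 minus A2iL-P9 was 10.7 calls and 7 private SNVs. Leaving out each library gave p from 0.0212 to 0.183 for private SNVs, from 0.0243 to 0.242 and 0.00847 to 0.175 for allele fraction of all and private calls (exact permutation), private LCDM SNVs against the rest from -5.375 to 6.625, condition sharing from 0.00762 to 0.0179, label-number sharing from -0.00824 to -0.00250 (passing without SL 3, exact permutation p = 0.0476, and LCDM 3, 0.0317), A2iL-P9 minus other P9 calls from -70.3 to 2160 (negative only without LCDM-P9 replicate 2) and A2iL-P14 minus A2iL-P9 private SNVs from -6 to 4. With label numbers 3 and 5 as a replicate block the exact permutation p was 0.4 for calls, 0.125 for private SNVs and 0.0167 for the private protein-changing share, and no call changed; between conditions, same-numbered minus other pairs were at -0.00260 (exact permutation p = 0.188, smallest possible 0.0625), so no pairing by number was seen. Leaving out clustered SNVs removed no ESC call, since none lie that close. The shares rest on 2 libraries per condition and 4 to 19 private protein-changing SNVs per library.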

Other observations

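The tests of explanations in this part, and the search over chromosomes, were chosen after the results were seen.

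At 350 sites outside segmental duplications called in all 10 ESC libraries with at least 20 reads, the 2iL-F libraries, grown without feeders, had a higher median fraction, 0.344 on average against 0.313 in the other 8 (difference 0.0308, exact permutation, two-sided p = 0.0222, the smallest possible). This p is not adjusted over the 5 conditions, after which a single condition cannot go below 0.111. The preset F test of allele fraction over all calls did not pass (exact permutation p = 0.0899). A gain of chromosomes 6 and 8 is argued against as the whole cause, since the difference was 0.0293 without these chromosomes (308 sites). A few sites are argued against by 68.6% of the sites being higher (240 of 350, Wilson interval 63.5 to 73.2%). Feeder DNA diluting the libraries grown with feeders may contribute. The ratio of 2iL-F to the rest was 1.08 at the sites of lower and 1.09 at those of higher fraction (175 each). Any rise across most sites would give such ratios, so they lend this explanation no support. Dilution by feeder DNA cannot be told apart from an effect of the condition, because only 1 of the 5 conditions lacked feeders.

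Read depth over the control at the same sites was tested for 2iL-F against the rest on 19 chromosomes. Chromosomes 6, 8 and X reached the smallest possible p of the exact permutation test, 0.0222 (two-sided), and none passed the adjustment over the 19 chromosomes (lowest adjusted p 0.141). The log2 depth of chromosome 6 was 0.29 and 0.23 in the 2iL-F libraries and -0.02 to 0.14 in the other 8 (17 sites), and that of chromosome 8 was 0.38 and 0.47 against 0.10 to 0.30 (25 sites). Chromosome X was lower in 2iL-F, with a mean of -0.47 against -0.31 (difference -0.16, 13 sites).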
